A study of Mus musculus with 48 samples.

How the data were processed

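Messenger RNA was sequenced from 4 hindlimb muscles of male FVB/NJ mice, an inbred laboratory strain, at embryonic day 18.5 (E18.5) and in adulthood. There were 6 animals per stage and 1 library per animal and muscle, which gave 48 libraries. Per the labels' protocols, soleus and vastus intermedius were chosen as muscles rich in slow fibres, and gastrocnemius and vastus lateralis as muscles poor in them. Soleus and gastrocnemius lie in the shank, and the 2 vastus muscles lie in the thigh. The series design text puts the adults at postnatal day 56, whereas the growth protocol gives a higher age at which adult mice were obtained, so the stage is called adult here. Per the labels, RNA with an integrity number above 7 was made into mRNA libraries with random-primed cDNA.

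The authors deposited 1 table of raw read counts per gene for the 48 libraries, with no normalization. Per the submitters' processing notes, the tools were FastQC 0.11.5, Trimmomatic 0.39.0, STAR 2.7.11, featureCounts of Subread 2.0.6 and DESeq2 1.44.0, and the genome build was mm10. The gene annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping and antisense genes could not be told apart. The myosin heavy chain genes, the actins and other close paralogs can share reads, and their counts are uncertain to that extent. The authors also deposited 9 tables of their own comparisons, which hold log2 fold changes and adjusted p-values. The direction of each was found from the signs of the log2 fold changes refitted with DESeq2 1.42.0. The authors' deposited tables were coded slow-biased minus fast-biased, thigh minus shank and E18.5 minus adult.

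The count table held 27179 genes. Symbols were taken from the RefSeq table of assembly GRCm38.p6 for 25275 identifiers and from the deposited comparison tables for 6, and 1898 genes had none. Total counts per library ranged from 14.9 to 32.4 M (median 22.8 M). The 20 most abundant genes took 11.3% to 45.5% of a library. A count of 0 allowed up to 3 counts, which was 0.093 to 0.201 CPM over the libraries. Intervals and floors given here cover counting error only. No 2 libraries of a group agreed within sampling noise, since the lowest chi-square per degree of freedom of such a pair was 10.23, and all 48 libraries were kept as separate samples.

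Each column of the count table names its stage, its muscle and a date tag, but not the animal number of the labels. The 6 tags of each stage, a date with or without a letter, were lettered A to F and are called collections. E18.5 collections C, D and E share 1 date and so do adult D and E, which leaves 4 dates at E18.5 and 5 in adults. Whether embryos of 1 date share a litter is not given in the sources used here, and date was not modelled. Letters do not link the stages. The labels say that all 4 muscles were taken from the same mice, and each tag had 1 library of each muscle, so the collection was used as the animal. Deviations from the group means correlated between libraries of the same collection by 0.188 on average at E18.5 and 0.068 in adults, against -0.037 and -0.014 between collections. The pairing rests on the tags and the labels. The tests between muscles had no block for the collection, as fixed before the data were examined, and a fit with the block was an alternative.

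Counts were tested with edgeR 4.0.16 (quasi-likelihood F tests, TMM normalization, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Muscle entered as 4 levels, in 1 fit per stage. Slow-biased minus fast-biased was the mean of soleus and vastus intermedius less the mean of gastrocnemius and vastus lateralis, and thigh minus shank was formed likewise. Each muscle pair, the difference of the 2 pairs (soleus minus gastrocnemius, less vastus intermedius minus vastus lateralis) and the difference of the slow-to-fast contrast between stages were also tested. Adult against E18.5 was tested on the summed counts of the 2 slow-biased or the 2 fast-biased muscles of each animal, 6 animals against 6. Errors of log2 fold changes are standard errors (SE), the fold divided by the square root of F. CPM are TMM-scaled and given as mean ± SD. Bounds against a floor, count ratios and the CPM beside them use total counts without TMM. Adult muscles read lower and E18.5 muscles higher on that scale, so falls with age read larger and rises smaller. P-values of other tests are exact and two-sided.

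Shares of 6 myosin heavy chain genes (Myh7, Myh2, Myh1, Myh4, Myh3 and Myh8) in their summed counts were compared within animals by exact sign flips and between stages by exact permutation, 48 tests in 1 family. Gene lists were tested with camera and fry of limma 3.58.1, camera with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. The 28 lists held 516 entries, of which 501 were found, and 27 lists could be tested. The lists were slow sarcomere, fast sarcomere, developmental sarcomere, fibre type regulators, satellite cells and myogenic factors, glycolysis and glycogen, nuclear-encoded oxidative phosphorylation, fatty acid uptake and oxidation, tricarboxylic acid cycle, limb patterning transcription factors, cell cycle, extracellular matrix, fibroblast, tendon, cartilage and bone, Schwann cell and nerve, neuromuscular and myotendinous junction, endothelial, pericyte and smooth muscle, adipocyte, leukocyte, erythroid, muscle spindle, imprinted growth genes, immediate early and stress, circadian clock, and atrophy and growth control. The mitochondrially encoded list had no gene in the count table used here and was not analysed here. Beside counts over all genes, calls adjusted over the list alone are given where they differed much.

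The genes named were set by a rule. Part (a) took the 6 largest positive and the 6 largest negative log2 fold changes among genes past the threshold with at least 5 CPM on the higher side, the same sign in every animal (for stage, groups that do not overlap) and a symbol that is not a predicted model. Part (b) took from each described list up to 4 members with the smallest adjusted p, and up to 2 that did not pass with the highest CPM. Part (c) named the 6 myosin genes above and, among others, Tnnt1, Tnnt3, Sox6, Tbx15 and Pvalb. Some genes that the rule selects were not used here.

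The alternatives were RLE and upper-quartile scaling, DESeq2, limma-voom with the animal as a random effect, other filters on low counts, library sizes without the 20 most abundant genes, leaving out each animal, the collection as a block, a fit of all 48 libraries and other groupings of the muscles. Fits without 1 doubted adult library, and E18.5 tests without 1 collection, were chosen after seeing the data. The scripts were tested on simulated counts of the real means and library sizes with genes changed 1.5, 2 or 4-fold. For adult slow against fast muscles, 50.7%, 73.1% and 89.4% of the changed genes were recovered among 14081 genes, and for the E18.5 contrast 68.7%, 85.1% and 98.5% were. For the contrast between stages the shares were 32.8%, 50.7% and 83.3%, and for the adult difference of the 2 muscle pairs 9.0%, 34.3% and 74.2%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.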

Results

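The series measured gene expression in 4 hindlimb muscles of male mice before birth, at E18.5, and in adults. Soleus and vastus intermedius are slow-biased muscles, with many fibres that use slow myosin, and gastrocnemius and vastus lateralis are fast-biased. Each of the 8 groups of muscle and stage held 6 libraries from 6 animals. Totals ranged from 14.9 to 32.4 M counts per library. The design asks how slow-biased and fast-biased muscles differ at each stage, whether that difference changes with age, and how thigh and shank muscles differ.

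Stage was the main axis of variation. The first principal component took 75.6% of the variance of log2 CPM and parted adult from E18.5 libraries, and the second took 9.8% and ordered the adult muscles from soleus to vastus lateralis. One library lay apart from its label. The library labelled adult vastus intermedius of collection B lay 41.4 units from the E18.5 centroid and 207.5 from the adult centroid. It held 8916 CPM of Myh3, the embryonic myosin heavy chain, against 6.18 to 22.8 CPM in the other 5 libraries of that group and 10890 ± 2374 CPM (SD, n = 6) in E18.5 vastus intermedius. Igf2, a fetal growth factor, was at 8345 CPM there, against 34.3 to 57.8 CPM in the other 5. The library was kept under its label, and the counts and the calls it changed are given with and without it.

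**Figure D1:**
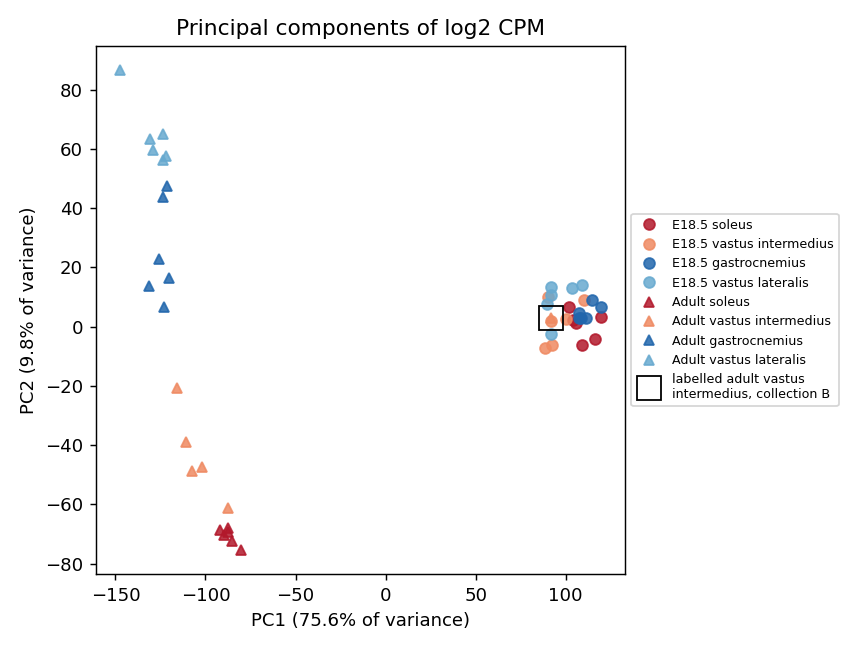
Scores of the 48 libraries on the first (x axis, 75.6% of variance) and second (y axis, 9.8%) principal components of log2 CPM, with 1 point per library, coloured by muscle and shaped by stage. Adult libraries lie on the left and E18.5 libraries on the right, and the boxed point, the library labelled adult vastus intermedius of collection B, lies among the E18.5 libraries.

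Refits with DESeq2 were set beside the authors' deposited comparisons. With the 23 other adult libraries, the refit gave the log2 fold changes of the authors' deposited table for adult slow against fast muscles (correlation across genes 1, median absolute difference 2.31e-06), and with all 24 the difference was 0.0537. The authors' deposited tables for E18.5 and for the fast-biased muscles matched refits with all libraries, with median absolute differences of 2.22e-06 (slow against fast), 3.31e-06 (region) and 3.28e-06 (fast-biased muscles). The authors' deposited table called 9744 genes for adult slow against fast muscles, of which 8295 were also called here with all libraries and 9087 without that library. The authors' deposited table for adult region called 231 genes, against 1118 here with 135 shared, and 2736 here without that library with 228 shared. The authors' deposited table for E18.5 slow against fast muscles called 107 genes, of which 44 were among those called here. The counts called here come from edgeR with each muscle as its own level, not from the DESeq2 refits. With muscle entered only as thigh or shank, edgeR called 10 genes for adult region with all libraries. With muscle entered only as slow-biased or fast-biased, it called 12 at E18.5. The gaps between these counts and the authors' therefore cannot be put down to that library alone.

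In adult muscle, genes of the slow contractile apparatus were far higher in the slow-biased muscles. Myl3, the slow and ventricular essential light chain, differed by a log2 fold change of 8.44 ± 0.66 (SE, n = 6 animals, adjusted p = 2.65e-10), and Myh7, the slow myosin heavy chain, by 8.22 ± 0.92. The regulatory light chain gene Myl2 (7.85 ± 0.71), Myh6 (7.74 ± 0.74) and the slow troponin genes Tnni1 (7.39 ± 0.68) and Tnnt1 (7.33 ± 0.65) followed, as did Sln, which encodes the calcium pump inhibitor sarcolipin. Genes lower in the slow-biased muscles included Odf3l2 (-6.76 ± 0.47), Myh4, the IIb myosin heavy chain (-6.74 ± 0.61), Mss51 (-6.31 ± 0.50), the transcription factor gene Six2 (-6.14 ± 0.33) and Cntnap2 (-6.00 ± 0.47). Actn3, the fast alpha-actinin, and Pvalb, a calcium buffer of fast fibres (-5.66 ± 0.56), were lower as well. In all, 8813 of 14220 genes passed the test, 4858 higher and 3955 lower in the slow-biased muscles, and 2865 of them differed more than 2-fold. Without the library labelled adult vastus intermedius of collection B, 9441 passed, 5139 higher and 4302 lower.

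Myosin heavy chain shares set the adult muscles apart. Myh7 (Entrez 140781) made up 58.2% ± 6.24 (SD, n = 6) of the 6 myosin transcripts in soleus, 9.94% ± 8.35 in vastus intermedius, 0.593% ± 0.541 in gastrocnemius and 0.00141% ± 0.00313 in vastus lateralis, where collection A was at 0.00777% and the other 5 at 0 to 0.000638%. Without the doubted library the vastus intermedius share was 11.5% ± 8.32 (n = 5). Myh4 (Entrez 17884) made up 91.9% ± 6.02 in gastrocnemius and 99.1% ± 0.754 in vastus lateralis, but 0.266% in soleus and 21.3% ± 22.8 in vastus intermedius. Myh2 (Entrez 17882), the IIa myosin, took 32.7% ± 6.87 in soleus and 28.1% ± 16.7 in vastus intermedius, and Myh1 (Entrez 17879), the IIx myosin, took 8.81% ± 3.46 and 24.8% ± 15.7. In vastus intermedius without the doubted library these were 25.4% ± 22.8 for Myh4, 33.4% ± 11.7 for Myh2 and 29.6% ± 11.4 for Myh1 (n = 5). The Myh7 share was higher in soleus than in gastrocnemius by 57.6 points and in vastus intermedius than in vastus lateralis by 9.94 points, in 6 of 6 animals each. The exact sign-flip p was 0.03125 for both, the smallest that 6 animals allow (adjusted p = 0.0429). Without the doubted library it was 0.0625 for the vastus pair, the smallest that 5 animals allow (adjusted p = 0.0769), and the soleus pair kept its 6 animals (adjusted p = 0.0484). Over the 48 share tests, 35 passed, and 18 to 19 did when any 1 animal of either stage was left out. The Myh7 calls of both adult pairs were then lost (adjusted p = 0.0536 to 0.0811). With an adult animal left out this was fixed in advance, since 5 animals allow no sign-flip p under 0.0625. With an E18.5 animal left out the p stayed at 0.03125 and only its adjustment changed.

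**Figure D2:**
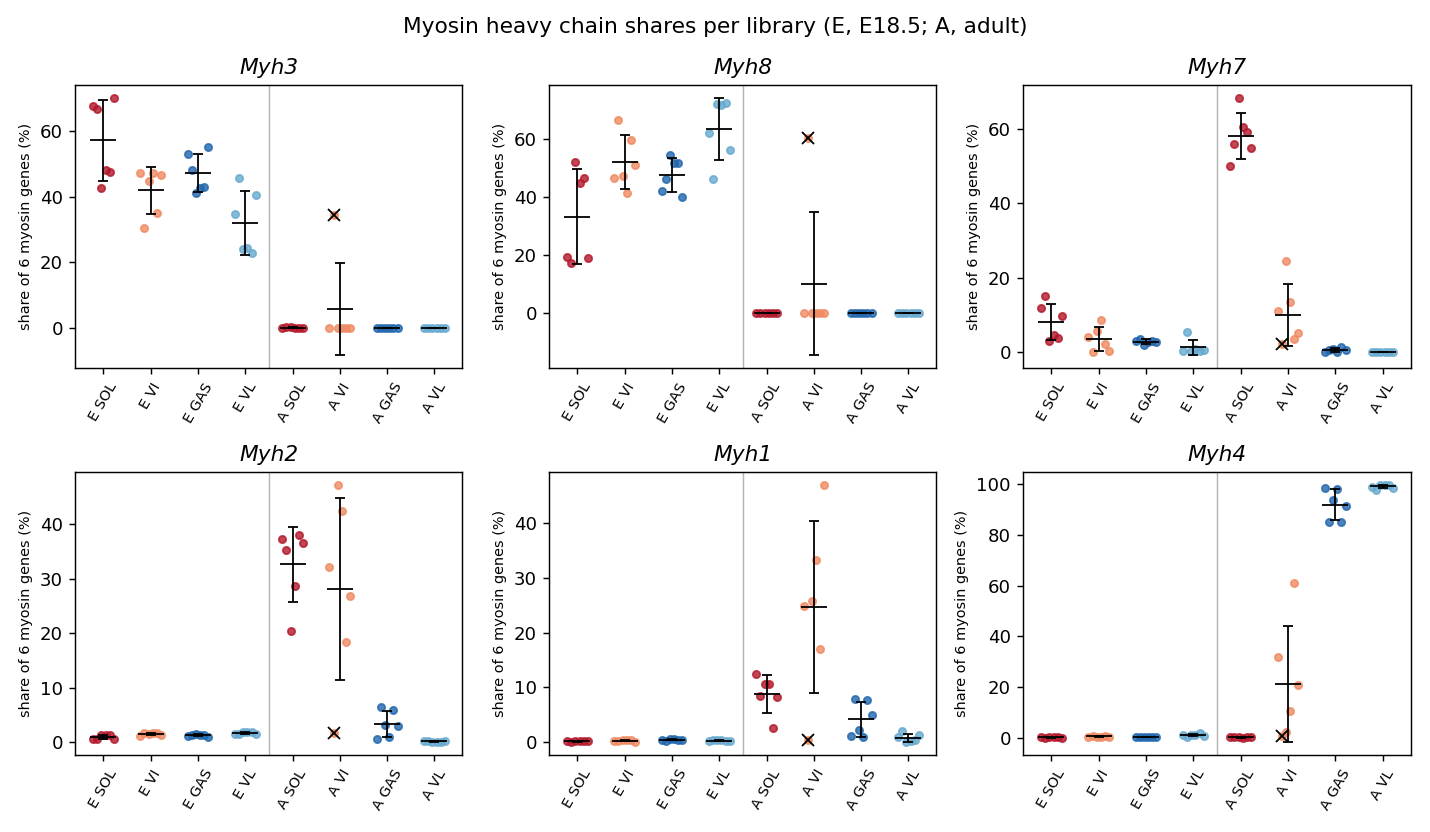
Share (y axis, percent) of each of 6 myosin heavy chain genes in their summed counts, 1 panel per gene, by muscle and stage (x axis), with 1 point per library and bars for the mean ± SD of 6 libraries. Adult gastrocnemius and vastus lateralis are almost wholly Myh4, E18.5 muscles are mostly Myh3 and Myh8, and the cross marks the library labelled adult vastus intermedius of collection B.

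All 16 slow sarcomere genes were higher in the adult slow-biased muscles (camera adjusted p = 4.68e-15, and adjusted p = 0.108 with an estimated correlation). They included Myoz2 (7.01 ± 0.50), Ankrd2 (6.34 ± 0.44) and Csrp3 (5.98), which encode Z-disc proteins. Of 16 fast sarcomere genes 13 were lower, 2 higher and 1 did not pass (adjusted p = 3.55e-13, and adjusted p = 0.108 with an estimated correlation). Casq1, the fast calsequestrin, had a log2 fold change of -2.68 ± 0.15, and Myoz1 (-2.79), Mylk2 (-3.01) and Tnnt3, fast troponin T (-2.05 ± 0.19), were also lower. The 2 that were higher were the IIa and IIx myosins Myh2 (4.18 ± 0.44) and Myh1 (1.52 ± 0.54, adjusted p = 0.0168), and Myh13 did not pass (0.08, adjusted p = 0.867). The 40 fibre type regulators went both ways, 16 higher and 12 lower (adjusted p = 0.409), and the list's median of 0.12 and mean of 0.06 had the opposite sign to its test. Prox1, a transcription factor of slow fibres, was higher (3.54 ± 0.25), and Sox6 (-1.73 ± 0.13), Tbx15 (-1.58 ± 0.10) and Nfatc3 (-0.75 ± 0.05), which act in the fast programme, were lower. Mef2c did not pass (-0.07, adjusted p = 0.534).

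Energy metabolism genes parted by pathway in the adult. Of 26 glycolysis and glycogen genes, 19 were lower in the slow-biased muscles and 4 higher (adjusted p = 3.05e-14, and adjusted p = 0.159 with an estimated correlation). The lactate exporter gene Slc16a3 (-3.61 ± 0.25), Gpd1 (-3.38 ± 0.20) and Pgm1 (-2.37) were lower, and Gys1 did not pass (0.20, adjusted p = 0.276). Of 25 fatty acid uptake and oxidation genes, 22 were higher and 1 lower (adjusted p = 3.24e-06, and adjusted p = 0.658 with an estimated correlation). They included lipoprotein lipase, Lpl (2.74 ± 0.31), the fatty acid transporter gene Cd36 (2.19 ± 0.22) and Acadm (1.47). Of 34 oxidative phosphorylation genes 8 were higher and none lower, or 4 adjusted over the list alone, and the list did not pass (adjusted p = 0.228). Without the library labelled adult vastus intermedius of collection B, 27 were higher and the list passed (adjusted p = 0.00138, and adjusted p = 0.635 with an estimated correlation). Tricarboxylic acid cycle genes went both ways, 5 higher and 2 lower of 15 (adjusted p = 0.409, and 0.0462 without that library, which was adjusted p = 0.635 with an estimated correlation), with Idh2 at 3.01 ± 0.27 and Idh3a at -0.70 ± 0.12.

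Markers of other cell types also differed between adult slow-biased and fast-biased muscles. All 14 endothelial genes were higher in the slow-biased muscles (adjusted p = 3.28e-06, and adjusted p = 0.159 with an estimated correlation), among them Kdr (0.96 ± 0.10), Pecam1 (0.77) and Emcn (0.70). Extracellular matrix genes were higher in 24 of 27 cases (adjusted p = 0.00199, and adjusted p = 0.658 with an estimated correlation), and 20 without that library. Leukocyte markers were higher in 10 of 12 cases (adjusted p = 0.0213, and adjusted p = 0.658 with an estimated correlation). Pericyte and smooth muscle genes (9 higher, 1 lower of 12) and muscle spindle genes (4 higher, 1 lower of 6) both had an adjusted p of 0.0601, and for spindle genes it was 0.04 with the collection as a block. Erythroid genes were higher in 3 of 3 cases (adjusted p = 0.122, and 0.0321 with the block). Schwann cell genes (8 higher of 10, adjusted p = 0.104), fibroblast genes (8 higher, 1 lower of 12, adjusted p = 0.107), tendon genes (5 higher of 11, adjusted p = 0.369), adipocyte genes (3 higher of 11, adjusted p = 0.45) and cartilage and bone genes (3 higher, 2 lower of 6, adjusted p = 0.819) did not pass as lists.

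In the adult the numbers of developmental sarcomere, cell cycle and imprinted growth genes called changed with the doubted library. Of 11 developmental sarcomere genes, 10 were higher in the slow-biased muscles (adjusted p = 0.0159, and adjusted p = 0.658 with an estimated correlation), and without the library labelled adult vastus intermedius of collection B 8 were higher and 1 lower (adjusted p = 0.00389, and adjusted p = 0.148 with an estimated correlation). Myh3 had a log2 fold change of 5.96 ± 1.14, which was 2.57 ± 0.45 without that library. Myh8, the perinatal myosin, had 4.14 ± 1.07 (adjusted p = 0.00194), which was -0.21 ± 0.20 (adjusted p = 0.353) without it. Cell cycle genes were higher in 15 of 21 cases with that library and in 3 without it (adjusted p = 0.474 and 0.714), and imprinted growth genes in 10 of 13 and in 6 (adjusted p = 0.169 and 0.317). The lists that follow are given with all libraries. Satellite cell and myogenic genes were mostly higher (13 of 17, adjusted p = 0.107), but Myod1 was lower (-1.77). Neuromuscular junction genes were split 6 to 6 of 14 (adjusted p = 0.819), and immediate early genes (6 higher, 1 lower of 15, adjusted p = 0.347), circadian clock genes (1 higher, 7 lower of 15, adjusted p = 0.279) and limb patterning genes (16 higher, 8 lower of 37, adjusted p = 0.347) did not pass. Atrophy and growth control genes did not pass as a list (8 higher, 1 lower of 14, adjusted p = 0.45), although myostatin, Mstn, a growth inhibitor, was much lower (-5.23 ± 0.37).

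The 2 adult muscle pairs shared most of these calls. Soleus and gastrocnemius differed at 5898 genes (2812 higher, 3086 lower in soleus, but 3248 and 2651 with upper-quartile scaling), and vastus intermedius and vastus lateralis at 7142 (4011 higher, 3131 lower). Both pairs called 4508 genes, of which 4479 had the same sign, where independent lists would share 1472.7 of the same sign. Without the library labelled adult vastus intermedius of collection B the pairs gave 7657 (3958 higher, 3699 lower in soleus) and 7466 genes, and 5495 had the same sign in both. In the shank pair Myh4 was lower in soleus by the widest margin (-10.16 ± 0.99), with Actn3 (-9.39), Mss51 (-8.52), Odf3l2 (-8.31) and Pvalb (-7.60), and Sln (6.65 ± 0.92), Mhrt (5.61) and Sim1 (5.25) were higher. In the thigh pair the slow genes led, with Myl3 (12.30 ± 1.09), Myh7 (11.46 ± 1.47), Myl2 (11.38) and Tnnt1 (10.26) higher in vastus intermedius, and Kcns1 (-6.66) and Six2 (-5.55) lower. Over the 6 vastus lateralis libraries Myl3 had 32 counts and Myh7 171, so the size of these 2 folds rests on few counts.

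The size of the difference depended on the pair. For soleus minus gastrocnemius less vastus intermedius minus vastus lateralis, 214 genes passed, 55 positive and 159 negative. Myh7 was at -6.49 ± 1.48 (adjusted p = 0.0232), since its fold was 4.97 ± 1.11 in the shank and 11.46 in the thigh, and Myh4 was at -6.84 ± 1.04, with folds of -10.16 and -3.32. The larger Myh7 fold in the thigh rests on low values in vastus lateralis, at 0 to 9.41 CPM, against 15.2 to 1460 CPM in gastrocnemius. As a share of the myosins, the Myh7 difference was larger in the shank, at 57.6 points against 9.94. Tnnt1 (-5.85), Myh2 (-5.10) and the lactate exporter gene Slc16a3 (-3.09) were negative too, and Tph1 (2.85), Fst, which encodes follistatin (1.96), and Col4a5 (1.67 ± 0.22) were positive. The slow sarcomere list was lower in 10 of 16 genes (adjusted p = 9.47e-21, and adjusted p = 0.0455 with an estimated correlation), and the fast list in 7 of 16 (adjusted p = 2.01e-20, and adjusted p = 0.0358 with an estimated correlation). No oxidative phosphorylation gene of 34 passed by edgeR with that library, and 28 were lower without it. Wnt16, a signalling ligand, had no count in adult vastus lateralis and was at least 65-fold higher in the vastus intermedius without the doubted library, against a floor of 3 counts per library. Without that library 1159 genes passed, and without each collection in turn 104 (A), 739 (B), 126 (C), 126 (D), 79 (E) and 59 (F).

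At E18.5 the slow-biased and fast-biased muscles differed much less. Bmper, a secreted regulator of bone morphogenetic protein signalling, was lower in the slow-biased muscles (-1.43 ± 0.16, n = 6 animals, adjusted p = 5.98e-05), at 17.2 ± 3.06 CPM (SD, n = 6) in soleus and 51.3 ± 2.71 in gastrocnemius. The bone matrix protein gene Ibsp (5.73 ± 1.00, adjusted p = 0.00963) and the bone transcription factor gene Runx2 (1.69 ± 0.36) were higher. Vtn, which encodes vitronectin (-1.05 ± 0.20), Dnah14 (-1.10), Adcy5 (-0.92), Gstm2 (-0.86) and the transcription factor gene Irx3 (-0.89) were lower, and the Wnt receptor gene Fzd10 (0.72) was higher. In all, 58 of 15751 genes passed, 23 higher and 35 lower. The count was 212 with the collection as a block (110 higher, 102 lower), 273 by DESeq2 (158 higher, 115 lower) and 192 by limma-voom (88 higher, 104 lower), so the larger side depended on the fit. Without each collection in turn it was 17 (A), 237 (B, 140 higher and 97 lower), 16 (C), 10 (D), 32 (E) and 13 (F).

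The slow contractile genes did not pass one by one at E18.5, but leaned to the slow-biased muscles as a list. Myh7 had a log2 fold change of 1.59 ± 0.59 (adjusted p = 0.262), Myl3 1.61 ± 0.56 (adjusted p = 0.219) and Tnnt1 0.81 ± 0.24 (adjusted p = 0.133). None of the 16 slow sarcomere genes passed by edgeR over all genes, 11 were higher when adjusted over the list alone, and the list passed camera (adjusted p = 7.83e-10, and adjusted p = 0.282 with an estimated correlation). Without collection B, 10 of them were higher (adjusted p = 4.19e-20, and adjusted p = 0.0576 with an estimated correlation), with Myh7 at 2.31 (adjusted p = 0.0112), Myl3 at 2.54 ± 0.40 and Tnnt1 at 1.03 ± 0.20. Tendon genes (adjusted p = 9.7e-06, and adjusted p = 0.429 with an estimated correlation) and cartilage and bone genes (2 of 9 higher, adjusted p = 0.000724, and adjusted p = 0.265 with an estimated correlation) passed as lists. The oxidative phosphorylation list passed with a median of 0.15 and none of 35 genes called (adjusted p = 4.67e-08, and adjusted p = 0.708 with an estimated correlation). The adipocyte list passed with the block (adjusted p = 0.00826) and not without it (0.216). Regulators and fast genes of the adult contrast did not pass at E18.5, with Sox6 at -0.42 (adjusted p = 0.196), Tbx15 at -0.06 (0.857), Tnnt3 at -0.11 (0.918), Pvalb at -1.57 (0.189), Myh4 at -0.65 (0.298), Myh1 at -0.64 (0.381), Myh2 at -0.22 (0.819), Myh3 at 0.37 (0.128) and Myh8 at -0.33 (0.67).

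Myosin shares differed within the E18.5 shank. Myh3 (Entrez 17883) and Myh8 (Entrez 17885) together made up most myosin transcripts in all 4 muscles, with Myh3 from 32.1% ± 9.77 in vastus lateralis to 57.3% ± 12.3 in soleus and Myh8 from 33.3% ± 16.3 in soleus to 63.6% ± 10.8 in vastus lateralis (SD, n = 6). The Myh7 share was 8.00% ± 4.89 in soleus and 2.81% ± 0.587 in gastrocnemius, higher in soleus by 5.19 points in 6 of 6 animals (exact sign-flip p = 0.03125, adjusted p = 0.0429). That call was lost when any 1 animal of either stage was left out (adjusted p = 0.0577 to 0.0833). With an E18.5 animal left out this was fixed in advance, since 5 animals allow no sign-flip p under 0.0625. With an adult animal left out the p stayed at 0.03125 and only its adjustment changed. The loss therefore does not show that the difference rests on single animals. The Myh3 share was 10.1 points higher in soleus in 6 of 6 animals, and the Myh8 share differed by -14.5 points, higher in soleus in 0 of 6 (adjusted p = 0.0429 for both). All 3 differences were smaller in collections C, D and E, which share a date, at 0.92 to 1.86 points for Myh7, 1.58 to 5.51 for Myh3 and -6.91 to -2.20 for Myh8, against 7.00 to 11.39, 14.87 to 18.90 and -29.02 to -21.05 in A, B and F. In CPM neither Myh3 nor Myh8 passed, with Myh3 higher in 5 of 6 animals (adjusted p = 0.0882) and Myh8 in 2 of 6 (adjusted p = 0.154). In the thigh pair the Myh7 share was 3.50% ± 3.35 in vastus intermedius and 1.25% ± 2.05 in vastus lateralis, a difference of 2.25 points in 4 of 6 animals that did not pass (exact sign-flip p = 0.3125). Without collection B the vastus lateralis mean was 0.42% and the difference 3.77 points, and without D the difference was 1.09 points.

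The E18.5 muscle pairs gave few calls each. Soleus and gastrocnemius differed at 45 genes, 15 higher and 30 lower in soleus. Pla1a (-1.76, adjusted p = 0.000205), Bmper (-1.57 ± 0.23), Slitrk1 (-1.53), Susd5 (-1.45) and Avpr1a (-1.30) were lower, and Nbl1 (0.86, adjusted p = 0.00722), Gas2 (1.21), Fzd10 (0.87) and Pitx1, a hindlimb transcription factor gene (1.02, adjusted p = 0.048), were higher. The count was 101 with the block, and 14 without collection B, 9 without D, 26 without E and 17 without F. Vastus intermedius and vastus lateralis differed at 5 genes, among them Eps8 (-0.49 ± 0.07, adjusted p = 0.00347), Bmper (-1.28 ± 0.23, adjusted p = 0.0392) and Slco3a1 (0.53, adjusted p = 0.0473, and 0.105 with the block). That count was 100 without collection B, where Myh7 stood at 3.50 ± 0.65 (adjusted p = 0.0167) against 1.80 (adjusted p = 0.759) with it. It was 3 without A, 2 without C, 0 without D, 2 without E and 1 without F. The difference of the 2 E18.5 pairs had 0 genes past the threshold by edgeR, with 731 at an unadjusted p under 0.05, 31 by DESeq2, 6 by limma-voom and 2 with the block.

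**Figure D3:**
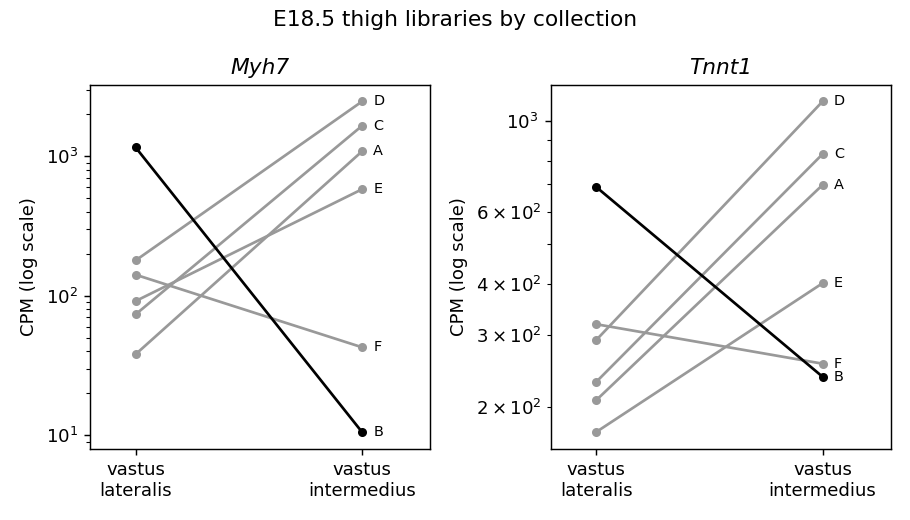
CPM on a log y axis of Myh7 and Tnnt1 in the E18.5 vastus lateralis and vastus intermedius libraries (x axis), with a line joining the 2 libraries of each collection. Collection B, in black, runs opposite to most others, with Myh7 at 1160 CPM in the library labelled vastus lateralis and 10.5 CPM in the library labelled vastus intermedius.

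The slow-to-fast difference itself changed between stages. For the adult contrast less the E18.5 contrast 8220 of 16248 genes passed, 4607 positive and 3613 negative, and 8336 passed without the library labelled adult vastus intermedius of collection B. The slow genes Sln (7.38 ± 0.64), Tnni1 (6.93 ± 0.61), Myl3 (6.82 ± 0.87), Myh7 (6.61 ± 1.01), Tnnt1 (6.50) and Myoz2 (6.44 ± 0.49) were more positive in the adult, and Kcns1 (-7.33), Mss51 (-6.29 ± 0.47), Myh4 (-6.09 ± 0.60), Trnp1 (-6.02), Cntnap2 (-6.00) and Pvalb (-4.11) more negative. The regulator genes Six2 (-5.11), Eya4 (-2.41), Tbx15 (-1.54), Sox6 (-1.32) and Nfatc3 (-0.77) were more negative in the adult as well. All 16 slow sarcomere genes passed as positive (adjusted p = 4.75e-21, and adjusted p = 0.0231 with an estimated correlation), and of 16 fast genes 12 were negative (adjusted p = 7.38e-08, and adjusted p = 0.327 with an estimated correlation). Glycolysis genes were negative in 18 of 26 cases (adjusted p = 2.85e-11, and adjusted p = 0.327 with an estimated correlation) and endothelial genes positive in 13 of 14 (adjusted p = 3.81e-05, and adjusted p = 0.327 with an estimated correlation). Oxidative phosphorylation genes did not pass as a list (2 of 35 positive, adjusted p = 0.86). Of the genes called in both stages, 36 in number, 21 had the same sign and 15 the opposite, and independent lists would share 15 of the same sign. Without E18.5 collection B these were 166, 128 and 38, against 67.1. Odf3l2 lost its call with the block (adjusted p = 0.0347 and 0.0824), and Myh8 lost its call without the doubted library (4.43, and 0.09 with adjusted p = 0.846 without it).

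From E18.5 to adulthood the fast-biased muscles exchanged developmental for adult contractile genes. Myh3 fell by 11.37 ± 0.54 on the log2 scale (SE, n = 6 animals per stage) and Myh8 fell by 10.13 ± 0.28, while Myh4 rose by 9.43 ± 0.36, Pvalb by 8.58 ± 0.57 and Myh1 by 5.45. The fetal acetylcholine receptor gene Chrng (-8.77), the fusion gene Mymk (-8.35), Sln (-9.37 ± 0.35) and the slow calsequestrin gene Casq2 (-5.99) fell, and Chrne, the adult receptor subunit gene (5.64), and the fast calcium pump gene Atp2a1 (4.92) rose. Tuba8 (10.33 ± 0.25) and Chac1 (10.23) rose and Arhgap36 (-12.42) fell. Igf2bp1, an oncofetal RNA-binding protein gene, had no count in the adult fast-biased muscles. By total counts without TMM it was at least 643-fold below its E18.5 level of 85.3 ± 27.3 CPM, and Cyp2e1 was at least 114-fold higher in the adult. Trpm5 fell to 1 count, a ratio of 1.35e+04 (95% counting interval 2427 to 5.34e+05). In all 13196 of 15759 genes passed, 6155 higher and 7041 lower in the adult. Myh2 rose by 2.69 ± 0.42 over both muscles but was at -1.52 in vastus lateralis alone. Of 16 slow sarcomere genes 8 fell and 1 rose, and the list did not pass (adjusted p = 0.422), with Tnnt1 lower (-1.64 ± 0.62, adjusted p = 0.0237) and Myh7 at -0.10 ± 0.74 (adjusted p = 0.903, and 0.026 by limma-voom). In vastus lateralis alone Myh7 fell from 280.7 CPM to 1.72 CPM with all libraries (exact permutation, adjusted p = 0.00649). Its E18.5 mean was 104.8 CPM without E18.5 collection B, and its adult mean 0.186 CPM without adult collection A. The call was lost when any 1 adult animal was left out (adjusted p = 0.0649). In gastrocnemius Myh7 was at 439.9 CPM at E18.5 and 691.5 CPM in the adult (adjusted p = 0.35). As a share of the myosins Myh7 fell in both muscles (adjusted p = 0.00693 for each). With any 1 adult animal left out, gastrocnemius kept its call (adjusted p = 0.00799 to 0.0139) and vastus lateralis lost it (0.0779 to 0.0811). The vastus lateralis difference was -1.25 points, and -0.419 without E18.5 collection B. Its shares did not overlap either, at up to 0.00777% in adults and from 0.167% at E18.5.

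Proliferation, matrix and growth genes fell in the fast-biased muscles with age. All 26 cell cycle genes fell (adjusted p = 3.74e-25, and adjusted p = 0.0467 with an estimated correlation), such as Top2a and Cdk1 (-7.00), and all 14 imprinted growth genes fell (adjusted p = 5.38e-21, and adjusted p = 4.2e-05 with an estimated correlation), such as Dlk1 (-9.59), Igf2 (-8.01), Mest (-7.25) and Cdkn1c (-6.07). All 12 developmental sarcomere genes fell (adjusted p = 1.43e-11, and adjusted p = 0.000427 with an estimated correlation). Of 27 matrix genes 25 fell (adjusted p = 7.88e-12, and adjusted p = 0.255 with an estimated correlation), including Postn (-7.07), and of 18 satellite cell and myogenic genes 14 fell (adjusted p = 0.0199, and adjusted p = 0.361 with an estimated correlation), including Msc (-4.39), Myog (-4.24) and Pax7, the satellite cell marker (-2.98). All 26 glycolysis genes rose (adjusted p = 2.42e-09, and adjusted p = 0.308 with an estimated correlation), such as Phka1 (5.72 ± 0.11), Aldoa (3.60) and Pfkm (3.54), as did 32 of 35 oxidative phosphorylation genes (adjusted p = 2.42e-09, and adjusted p = 0.483 with an estimated correlation). Among 40 fibre type regulators 28 rose and 9 fell (adjusted p = 0.00068, and adjusted p = 0.0467 with an estimated correlation), led by the thyroid hormone receptor gene Thrb (7.07 ± 0.18), with Sox6 (2.56), Nfatc1 (2.09) and Tbx15 (1.85). Clock genes rose in 13 of 15 cases (adjusted p = 0.000693, and adjusted p = 0.114 with an estimated correlation), among them Bhlhe41 (4.89), Dbp (4.27) and Tef (2.68), and of the atrophy list Fbxo32 (6.87) and Trim63 (3.46) rose.

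The slow-biased muscles gained slow and oxidative genes with age. Myh7 rose by 3.70 ± 0.31 (n = 6 animals per stage), the slow calcium pump gene Atp2a2 by 4.03 ± 0.21, Tpm3 by 3.48 and Tnnt1 by 2.37, and Myh1 (7.40 ± 0.64), Pvalb (6.34), Myh2 (5.69 ± 0.37) and Tnnt3 (1.60) rose as well. Of 16 slow sarcomere genes 13 rose and 2 fell (adjusted p = 3.58e-06, and adjusted p = 0.551 with an estimated correlation). All 25 fatty acid genes rose (adjusted p = 1.82e-19, and adjusted p = 0.551 with an estimated correlation), such as Fabp3 (4.82 ± 0.25), Eci1 (3.54) and Hadhb (3.46), as did 34 of 35 oxidative phosphorylation genes (adjusted p = 6.99e-15, and adjusted p = 0.551 with an estimated correlation), such as Cox8b (3.84), and 22 of 26 glycolysis genes (adjusted p = 3.88e-06, and adjusted p = 0.551 with an estimated correlation). Thrb (7.16 ± 0.45), Fbxo32 (6.05 ± 0.33), Sox6 (1.29) and Tbx15 (0.31) rose. Of 11 adipocyte genes 9 rose (adjusted p = 0.000171, and adjusted p = 0.551 with an estimated correlation), with Plin1, a lipid droplet protein gene, at a ratio of 1421 (95% counting interval 393 to 1.17e+04) over 2 E18.5 counts. Retnla had no E18.5 count and was at least 231-fold higher in the adult by total counts without TMM. In all 12175 of 15900 genes passed, 5974 higher and 6201 lower, and 12763 without the animal of the doubted library. That animal decided several developmental genes. Myh3 was at -3.51 ± 1.57 (adjusted p = 0.0575) and -9.19 ± 0.38 without it, Myh8 at -2.69 ± 1.72 (adjusted p = 0.17) and -9.92 ± 0.36, and Dlk1 at -3.26 ± 1.87 (adjusted p = 0.129) and -12.52 without it.

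Both muscle types called 10686 genes between stages, of which 10244 changed in the same direction and 442 in opposite directions, where independent lists would share 5015.9 of the same direction. Upper-quartile scaling moved the median log2 fold change of all genes from -0.029 to -0.142 in the slow-biased and from -0.121 to -0.264 in the fast-biased muscles. The log2 fold changes above are relative to TMM scaling, and the bounds and count ratios to total counts.

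In the adult, thigh and shank muscles differed in limb position genes and in fibre genes. Tbx5, a limb transcription factor gene, was higher in the thigh (4.08 ± 0.41, n = 6 animals), at 3.50 ± 1.47 CPM in vastus intermedius and 2.40 ± 1.09 in vastus lateralis against 0.159 ± 0.136 in gastrocnemius and 0.182 ± 0.169 in soleus. Within vastus intermedius the doubted library was at 5.76 CPM and the others at 1.90 to 4.41 CPM. Hoxc8 (1.52) and Hoxc6 (1.32) were higher in the thigh, and Hoxc11 (-1.48) lower. Slow genes were lower in the thigh, Myl2 (-5.43 ± 0.65), Myl3 (-5.39), Myh7 (-5.34 ± 0.81), Myh6 (-5.08), Tnnt1 (-4.84) and Tnnc1 (-4.82), and Tmem132b (4.11 ± 0.56), Myh4 (3.78 ± 0.53), Mybph (3.72), Actn3 (3.44) and Pvalb (2.62) were higher. Mean Myh4 was 144200 CPM in vastus lateralis, 113900 in gastrocnemius, 14560 in vastus intermedius and 98.7 in soleus. Mean Myh7 was 21560 CPM in soleus, 5002 in vastus intermedius, 691.5 in gastrocnemius and 1.72 in vastus lateralis. These 2 folds thus rest largely on 1 low muscle each, and vastus intermedius and gastrocnemius ran against the thigh to shank direction. Slow sarcomere genes were lower in 12 of 16 cases, or 15 adjusted over the list alone (camera adjusted p = 2.68e-36, and adjusted p = 0.00685 with an estimated correlation), fast genes higher in 12 of 16 (adjusted p = 1.15e-13, and adjusted p = 0.0608 with an estimated correlation) and glycolysis genes in 16 of 26 (adjusted p = 1.34e-10, and adjusted p = 0.296 with an estimated correlation). Tendon genes were lower in 3 of 11 cases (adjusted p = 1.88e-07, and adjusted p = 0.239 with an estimated correlation), among them Mkx (-1.65) and Scx (-0.96). Myh1 (0.05, adjusted p = 0.973) did not pass.

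The adult thigh to shank count was 1118 genes, 634 higher and 484 lower in the thigh, and 2736, 1656 higher and 1080 lower, without the library labelled adult vastus intermedius of collection B. It was 10 with 2 levels of muscle in place of 4, 2213 without the animal of collection B, 680 without D, 447 without E and 529 without F. Myh8 was at 4.14 (adjusted p = 0.0168) with that library and at -0.23 (adjusted p = 0.463) without it, and Shisal1 at 3.04 and 0.94 (adjusted p = 0.109). The oxidative phosphorylation list had none of 34 genes called by edgeR with it (adjusted p = 0.168) and 15 higher without it (adjusted p = 1.19e-07, and adjusted p = 0.564 with an estimated correlation). Cell cycle (adjusted p = 0.00129 and 0.369) and imprinted growth genes (0.00619 and 0.679) passed with it (adjusted p = 0.71 for both with an estimated correlation) and not without it, and the imprinted list did not pass with the block (0.0757).

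At E18.5 the thigh muscles stood above the shank muscles in contractile and metabolic genes. Tbx5 was again higher in the thigh (4.86, adjusted p = 2.15e-12), and the posterior limb genes Hand2 (-8.61 ± 0.73, with 5 counts over the thigh libraries, and at 0.87 and 0.0681 CPM in soleus of D and E against 6.87 to 14.3 CPM in the other 4), Hoxd10 (-4.19 ± 0.30) and Hoxd9 (-2.12 ± 0.26) were lower. Gpd1 (3.11 ± 0.34), Mybpc2, fast myosin-binding protein C (3.10 ± 0.51), Actn3 (3.10 ± 0.42), Rpl3l (3.03), Eef1a2, a muscle and nerve elongation factor gene (2.78), Pvalb (2.40), Myh4 (1.67), Myh2 (1.27) and Myh8 (1.20) were higher. In all 3909 of 15751 genes passed, 2217 higher and 1692 lower in the thigh, and 1863, 1517 higher and 346 lower, with all 48 libraries in 1 fit. Fast sarcomere genes were higher in 14 of 16 cases (adjusted p = 4.64e-15), glycolysis genes in 24 of 26 (3.05e-20), oxidative phosphorylation genes in 33 of 35 (5.78e-33) and tricarboxylic acid cycle genes in 15 of 15 (1.98e-20), each with adjusted p = 0.143 with an estimated correlation and 0.0125 to 0.0132 where that fit also held the collection as a block. Fatty acid genes were higher in 19 of 25 cases, or 25 adjusted over the list alone (adjusted p = 1.66e-16, and adjusted p = 0.21 with an estimated correlation). Examples were the cytochrome c gene Cycs (1.09 ± 0.13), Acsl1 (1.17), Pygm, muscle glycogen phosphorylase (1.21), and the glucose transporter gene Slc2a4 (1.08). Tendon genes were lower in 4 of 11 cases (adjusted p = 0.00343, and adjusted p = 0.624 with an estimated correlation), with Mkx (-1.45) and Scx (-0.69) called and Comp at -1.88 (adjusted p = 0.024, and 0.162 with the block). Of 16 slow sarcomere genes 5 were higher and 1 lower, and the list did not pass (adjusted p = 0.441). Myh7 (-0.44, adjusted p = 0.617), Tnnt1 (-0.36, 0.288) and Myh3 (0.21, 0.169) did not pass.

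**Figure D4:**
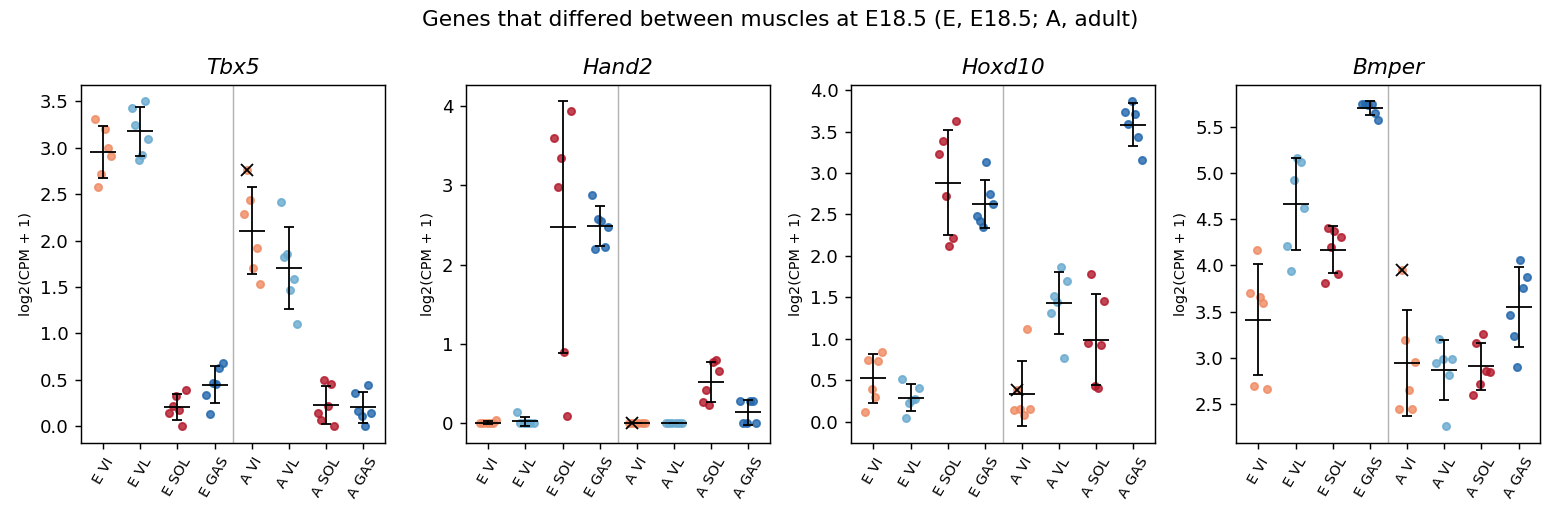
Expression (y axis, log2(CPM + 1)) of Tbx5, Hand2, Hoxd10 and Bmper by muscle and stage (x axis), with 1 point per library and bars for the mean ± SD of 6 libraries. Tbx5 is higher in the thigh at both stages, Hand2 and Hoxd10 in the E18.5 shank, where 2 soleus libraries have little Hand2, and the cross marks the library labelled adult vastus intermedius of collection B.

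Thigh against shank calls overlapped between stages, counted over genes of every kind. Single position genes differed in this. Tbx5 was higher in the thigh at both stages, but Hand2 was at most 0.736 CPM in any adult library. Adult Hoxd10 was at 0.326 to 2.43 CPM in soleus and 7.91 to 13.6 CPM in gastrocnemius. Of the 406 genes called for thigh against shank at both stages, 308 had the same sign and 98 the opposite, where independent lists would share 145.7 of the same sign. Without the doubted adult library these were 1125, 964 and 161, against 362.4. Limb patterning genes went both ways at both stages, 5 higher and 9 lower of 37 in the adult (adjusted p = 0.168) and 10 higher and 16 lower of 44 at E18.5 (adjusted p = 0.375).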

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

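The tests of an exchange between the stages, of a shared embryo and of the muscle-cell share, and the counts over other splits of the samples, were chosen only after the results they measure were seen. Of 96 groups of 6 libraries tested for a value far from the rest, 10 held one, where chance flags about 1 in 20 groups.

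The library labelled adult vastus intermedius of collection B stood apart with shares of 34.6% for Myh3 and 60.4% for Myh8, against 0.0133% to 0.0514% and 0.00926% to 0.0133% in the other 5. A mixture with adult RNA was argued against, since 43 genes over 50-fold higher in adult than in E18.5 vastus intermedius lay at a median of 0.855% of their adult level (quartiles 0.463% to 1.669%) and 94 genes over 50-fold higher at E18.5 lay at a median of 98.8% of theirs (91.09% to 105%). An exchange between the stages was argued against too, since 0 E18.5 libraries lay nearer to the adult centroid. RNA of an E18.5 muscle under a wrong label needs that low median and stays open as a candidate explanation, although 0.855% lay a little above the 0.278% to 0.762% of the E18.5 libraries, and no biological explanation was tested. The library may come from the embryo of E18.5 vastus intermedius of collection E, since their chi-square per degree of freedom of 4.56 lay under the 10.23 of the closest pair within any group, and the next E18.5 library was at 15.75.

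At E18.5 the vastus lateralis library of collection B stood apart with 5.42% Myh7 against 0.167% to 0.672%, and 690 CPM of Tnnt1 against 173 to 318. Of 100 genes that parted the 2 vastus muscles in the other 5 collections, 90% had the opposite sign in B, against 0% to 19% in each of the others, which had helped choose them, although collection F also had Myh7 lower in vastus intermedius (42.7 CPM) than in vastus lateralis (142 CPM), and Myl2, Tnnc1, Tnnt1 and Myl3 likewise. A vastus intermedius dissection with little slow muscle was argued against, since 97.1% of the 68 genes higher in vastus intermedius were above every other vastus lateralis library in that of B, while 67.6% were below every other vastus intermedius library in that of B. Bmper, which was lower in vastus intermedius with and without collection B, ran as labelled in B (5.48 CPM in vastus intermedius and 14.3 CPM in vastus lateralis), which an exchange would not give. It was among the few genes called with B included, a choice that favours genes that ran as labelled in B. This 1 gene therefore cannot decide against an exchange. An exchange of the 2 labels of collection B needs the opposite signs and stays open as a candidate explanation, no biological explanation was tested, and no library was relabelled.

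Contractile and metabolic genes were higher in the E18.5 thigh than in the shank. A difference in depth was argued against, since totals were 24.85 ± 2.83 M counts in the thigh and 23.56 ± 2.83 M in the shank (SD over 6 embryos, exact sign-flip p = 0.3125), a gap smaller than the SD. Thigh muscles may be further along the course from embryo to adult, since thigh minus shank and adult minus E18.5 shank folds from separate embryos correlated across genes at 0.307 and 0.33, although genes are not independent replicates and embryos of 1 date fell on both sides. A larger share of muscle cells in the thigh cannot be told apart from this, because 28 slow and developmental sarcomere genes had a median of 0.039 with quartiles of -0.352 to 0.566, which overlapped the 0.508 to 0.655 of 35 oxidative phosphorylation genes, and a difference of position as such stays open, untested.

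Values that stood apart without further weighing were as follows. Tbx15 was at 340 CPM in adult gastrocnemius of collection E, against 451 to 485 in the other 5. Pvalb was at 4320 CPM in adult vastus intermedius of collection E, against 22 to 1410. The 22 CPM was the library labelled adult vastus intermedius of collection B, and the lowest without that library was 239.7 CPM. In adult vastus lateralis of collection A the Myh7 share was 0.00777%, against 0 to 0.000638%, and Tnnt1 was at 4.64 CPM, against 0.128 to 0.563. The Myh3 share was 0.00957% in adult vastus lateralis of collection F, against 0.000404% to 0.00108%. The total of E18.5 gastrocnemius of collection F was 31.2 M counts, against 21.4 to 23.6 M.

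The slow-to-fast difference itself differed between stages at 8220 genes and between the adult muscle pairs at 214 genes, both by a test of the difference.

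Among 100 splits of the same samples, the real one included, the real one called the most genes for adult slow against fast muscles (8813 genes, 5234 in the highest other split), for its change with stage (8220, 1360), for adult soleus against gastrocnemius (5898, 2280), adult vastus intermedius against vastus lateralis (7142, 2176), adult thigh against shank (1118, 1), E18.5 thigh against shank (3909, 1577), E18.5 slow against fast muscles (58, 2), E18.5 soleus against gastrocnemius (45, 1) and stage in the fast-biased muscles (13196, 0). In each of these 1 split, the real one, gave as many genes. The same held for stage in the slow-biased muscles (12175), where the highest other split gave 9739 genes. A share of 1 in 100 is the smallest these splits allow. The splits between muscles shuffled all 4 muscle names within each collection, which removes every muscle difference together. They thus weigh whether the muscle names matter at all, and cannot exclude chance for 1 contrast apart from the others. For E18.5 vastus intermedius against vastus lateralis 2 splits gave at least the real 5 genes and the highest other gave 49, and for the adult difference of the muscle pairs 4 splits gave at least the real 214 and the highest other gave 3623. Since other splits gave counts several times the real one, the splits cannot exclude chance for either. Such counts point to a structure of the samples, whose source was not tested. For the E18.5 difference of the muscle pairs all 100 splits gave at least the real 0 genes, the highest other gave 6, and chance cannot be excluded.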

How the results depend on the processing

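The fits without the library labelled adult vastus intermedius of collection B, and the E18.5 list tests and the genes of both E18.5 pairs without collection B, were chosen after seeing the data, and the other alternatives were fixed earlier. Of 401 results of single genes followed across the alternatives, which include those named in the text, 363 passed, 280 of them in every alternative run for them. Over 7066 alternatives of the 363, 6789 kept the direction and the call, 268 fell below the threshold and 9 turned sign, and 15 results that had not passed did so in some alternative. Of 255 alternative counts of genes, 185 were within 1.5 times of the count reported. Depth was not varied, and a count of 0 left up to 0.093 to 0.201 CPM open in a library.

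With DESeq2 the counts were 273 for E18.5 slow against fast muscles, 163 and 21 for the E18.5 shank and thigh pairs, 457 for the adult difference of the pairs and 31 for the E18.5 one. With limma-voom they were 192, 131, 119 (adult difference) and 6. With the collection as a block they were 212 for E18.5 slow against fast, 101 for the E18.5 shank pair and 2 for the E18.5 difference. With all 48 libraries in 1 fit they were 22, 20 and 1 for the E18.5 contrast and its 2 pairs, 1863 for E18.5 thigh against shank and 2239 for adult thigh against shank. With 2 levels of muscle in place of 4 they were 12 for E18.5 slow against fast and 10 for adult thigh against shank. Genes past the threshold with the same sign in both pairs were 4479 in the adult, 5495 without that library, and 2 at E18.5, with and without collection B. Without that library, adult thigh against shank gave 2736 (3005 with the block, 3089 by DESeq2) and the adult difference of the pairs 1159 (1425 and 1424). Of 351 list tests 126 passed with the preset and 9 with the estimated correlation.

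Leaving out 1 animal at a time gave 7898 to 8999 genes for adult slow against fast, 10 (without D) to 237 (without B) for E18.5 slow against fast, 7548 to 8238 for the change with stage, 11834 to 12763 and 13041 to 13316 for stage in the slow-biased and fast-biased muscles, 447 (without E) to 2213 (without B) and 2869 to 3654 for thigh against shank in the adult and at E18.5, 4559 to 7127 and 6015 to 7019 for the adult shank and thigh pairs, 9 (without D) to 34 and 0 (without D) to 100 (without B) for the E18.5 shank and thigh pairs, and 59 (without F) to 739 (without B) and 0 to 1 for the adult and E18.5 differences of the pairs. Myosin share tests past the threshold were 35 of 48, 18 to 19 without 1 animal, where 5 sign flips cannot go below 0.0625, and 31 both for CPM and without that library.

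Myh8 turned sign in adult slow against fast muscles, at -0.10 without the animal of collection B (up to 4.43 without any other), -0.21 without that library, -0.18 with the block as well and -0.21 by DESeq2, and in adult thigh against shank, at -0.35 (up to 4.35), -0.23, -0.23 and -0.22. Myh2 turned sign between stages in vastus lateralis alone (-1.52). Apart from the fits that drop samples, the cause was not tested.

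Pairing by the collection changed the counts, genes and lists given with a block value in the report, and these lists: circadian (adjusted p 0.0365 with the block in adult and 0.0399 in E18.5 thigh against shank), fibroblast (0.0495, adult shank pair), oxidative phosphorylation and erythroid (0.0613 and 0.0132, adult thigh pair), imprinted (0.441, adult difference of pairs), pericyte (0.0808, E18.5 thigh against shank, and 0.0506, change with stage), tricarboxylic acid cycle, adipocyte, erythroid and spindle (0.00498, 0.00498, 0.00226 and 0.0604, E18.5 shank pair), glycolysis (0.0073, E18.5 thigh pair) and erythroid (0.00026, E18.5 difference of pairs). It changed no other list call or count past 1.5 times.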

Other observations

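The list tests were planned, and the genes named here were chosen after their values were seen. Single marker genes of cell types other than fibres changed with age in the fast-biased muscles, some in opposite directions within a list, and the lists given here did not pass. All 5 erythroid genes fell (camera adjusted p = 0.643), among them the alpha globin gene Hba-a1 (-2.15 ± 0.45). Of 15 leukocyte markers 9 fell and 3 rose (adjusted p = 0.66), with the mannose receptor gene Mrc1 lower (-2.40 ± 0.14) and the antigen presentation gene H2-Aa (4.71 ± 0.36) and the lysozyme gene Lyz2 (1.46 ± 0.16) higher. The neurofilament gene Nefl fell by 5.12 ± 0.56, within a Schwann cell and nerve list of 7 lower and 2 higher genes of 10 (adjusted p = 0.334). Among neuromuscular junction genes, 8 fell and 5 rose of 14 (adjusted p = 0.537), with the receptor subunit gene Chrnd (-4.71 ± 0.28) and Lrp4 (-1.70 ± 0.09) lower. The cartilage gene Acan fell by 10.27 ± 0.70, and Comp, a tendon and cartilage matrix gene, rose by 3.51 ± 0.30, in lists that did not pass (adjusted p = 0.622 for both).

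Of 11 tendon genes at E18.5 none passed by edgeR over all genes between soleus and gastrocnemius, 7 were higher in soleus when adjusted over the list alone, and the list passed (adjusted p = 6.26e-09, and adjusted p = 0.332 with an estimated correlation). The difference of the 2 muscle pairs also passed for tendon genes (adjusted p = 4.25e-05, and adjusted p = 0.719 with an estimated correlation). Pericyte and smooth muscle genes were lower in soleus as a list (adjusted p = 5.74e-05, and adjusted p = 0.332 with an estimated correlation), with 4 of 12 lower when adjusted over the list alone. Schwann cell genes were higher in vastus intermedius than in vastus lateralis as a list (adjusted p = 0.000837, and adjusted p = 0.683 with an estimated correlation), and none of its 10 genes passed by edgeR.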
